A study of Mus musculus with 12 samples.

How the data were processed

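Colon RNA of 12 libraries was analysed, 3 each from Control mice, mice given dextran sulfate sodium (DSS), and DSS mice given Banxia Xiexin Decoction at 7.60 (BXD_L) or 15.2 g/kg per day (BXD_H). RNA was extracted with TRIzol and libraries were made from 1 µg of total RNA with a NEBNext Ultra RNA kit, per the labels' protocols. The tools named in the submitters' processing notes are bcl2fastq, FastQC and fastp, without versions, and the build is mm10. The aligner, the counting program, its use of strand, the annotation release and the rule that selected the listed features are not given in the sources used here. The deposited values are FPKM with 2 decimals, 1 column per library, per the file headers. They are fragments per kilobase of gene, scaled to 1000000 fragments per library, so they are corrected for gene length and library total but not for composition. A gene taking a large share of fragments lowers the FPKM of all others.

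The Control and DSS files list the same 912 features, the BXD_L files 8 and the BXD_H files 95, 991 in all. Of these, 981 matched a gene of GENCODE release M21, whose build GRCm38 is that of mm10, by Ensembl identifier, and coordinates (1-based), gene class and exon length come from it. The other 10 kept their identifiers. The sum of listed FPKM is not a depth, because the lists are partial. Depth was therefore recovered from genes with exons under 1200 bases: for each library, totals between 5 and 30 times 1000000 fragments were scanned for the one at which FPKM times length gave whole fragments, within the rounding of the file and at most 0.2 fragments. At the chosen total 76.5 to 94.1% of 17 to 120 short genes were whole, against at most 58.8% (BXD_H) or 35.3% (Control and DSS) in 20 shuffles of the gene lengths. The totals assume that the annotated exon length is the one used by the authors, and they were not determined for BXD_L, which has 5 to 6 short genes. With totals of 12.4 to 19.2 times 1000000 fragments, FPKM values below 1 of short genes rest on few fragments. Library pairs of a group shared at most 25 equal values of 912, so no library was counted as a copy of another.

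Groups were taken from titles, which the treatment labels repeat. The description text of Control replicate 3 names DSS and that of DSS replicate 3 names BXD_L; both libraries stayed in the groups of their titles, and the fits without them and with the groups of the description text were run as alternatives. Values were tested as log2(FPKM + 1) with limma (version 3.58.1 in R 4.3.3), using 1 mean per group over all 12 libraries, each feature fitted on the libraries that list it, with a shared trended estimate of the spread. Features with an FPKM of at least 1 in 3 or more of the 12 libraries were tested, and p-values are two-sided with Benjamini-Hochberg adjustment over the features tested in that comparison and a threshold of 0.05. The design had provided for count-based tests as well; those were not run, since the files hold FPKM. Enrichment tests against a transcriptome were not run, since no transcriptome background is listed. The fit was tested on simulated values for DSS against Control with 607 features tested, of which 83.8% of 74 features changed by 1 on the log2 scale and 97.4% of 77 changed by 2 were recovered, and 2.84% of calls had no simulated change. That simulation changed 200 features, with as many rises as falls and no selection of features. The listed features are a selection with mostly rises, so these shares check the fit and do not describe the real calls.

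The design, the alternatives, 37 gene lists (783 genes) and the rule for named genes were fixed before the data were examined. The rule took, per comparison, up to 8 rises and 8 falls with the largest log2 change among features past the threshold whose 3 libraries in each group did not overlap and whose higher mean was at least 10 FPKM. It added up to 4 members of each list with the smallest adjusted p, every feature of a file with 30 or fewer features, and 12 genes set in advance. Where genes outside the rule are named, they complete a count or were chosen after their values were seen. For lists with 5 or more calls, 12 in number, rises and falls were compared with those of the other calls by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment. That test treats genes as independent, which genes of the same libraries are not. Camera tests were not run, as planned for files that hold a selection. The immunoglobulin segments were grouped by annotation after the data were seen.

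The reversal of DSS changes was measured as the share of features changed in DSS whose decoction mean lies on the Control side of the DSS mean, with an exact binomial 95% interval, beside 4000 simulated groups that differ from DSS in nothing and share its libraries. Features are not independent, so that interval covers counting error only. Simulated ranges hold the central 95% of the simulated groups. The simulation drew features independently, so the spread under chance may be wider. Alternatives changed one choice at a time, apart from centring: a pseudocount of 0.1, median-centred log2 values, no low-value filter, a fit of the compared groups alone, the replicate number as a block, each library left out in turn, the libraries of conflicting description left out or moved, an adjusted p of 0.01 and a log2 change beyond 1. The centred values were fitted on the compared groups alone, so that setting changed the estimate of the spread as well. Centring of the gene lists was added after the data were seen. Centring was not possible for comparisons with fewer than 10 shared features. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, exact tests and plots. Of the listed features, 5 of BXD_L and 76 of BXD_H have no value in Control or DSS and entered no comparison with them.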

Results

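RNA from mouse colon was sequenced in 12 libraries, 3 in each of 4 groups. Control mice drank plain water. DSS mice received 3 rounds of 2.5% dextran sulfate sodium, a sulfated polysaccharide that injures the colon lining, each round lasting 5 days and followed by 5 days of water. The BXD_L and BXD_H mice received the same course together with Banxia Xiexin Decoction, a multi-herb preparation of Chinese medicine, at 7.60 and 15.2 g/kg per day. The labels do not state that each library came from a separate mouse, so p-values measure the spread between these libraries, which may be technical. Each file listed only part of the transcriptome, as FPKM (fragments per kilobase of gene, scaled to the library total). The Control and DSS libraries held the same 912 features, the BXD_L libraries 8 and the BXD_H libraries 95, with 3 features shared between DSS and BXD_L, 19 between DSS and BXD_H and 2 between the doses. Of the 912 features, 745 were protein-coding genes and 61 were immunoglobulin segments. Every feature of the Control and DSS list differed between those groups by at least 1.87-fold in mean FPKM, and in 868 of the 912 the 3 libraries of one group all lay above those of the other, against 10% expected by chance for 3 against 3. The list is a selection, probably made on these same samples, so the number of calls below is not independent evidence of a difference, and adjusted p-values cover the listed features only. The spacing of low values implied library totals, in units of 1000000 fragments, of 14.4, 16.7 and 16.2 for Control, 15.4, 16.6 and 19.2 for DSS and 17.2, 18.2 and 12.4 for BXD_H. The BXD_L files held too few short genes to give a total. The description text of 2 libraries, Control replicate 3 and DSS replicate 3, names the next group, in conflict with their titles and treatment labels. The lists of features follow the titles, since both libraries hold the 912 features of Control and DSS. Groups followed the titles as well.

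The comparison of DSS with Control asks what the colitis course changed in the colon. Inflammatory mediators, immunoglobulin genes, leukocyte markers, extracellular matrix genes and proteases were higher in DSS, and transporters and enzymes of absorptive colonocytes were lower. Of 576 features that passed the low-value filter, 456 rose and 115 fell in limma's moderated test, and 5 did not pass (Prdx6, Bst1, Gm10222, Tgtp1 and Chil3). Plet1, an epithelial surface protein, rose from 2.09 ± 1.32 FPKM in Control to 55.4 ± 23.4 FPKM in DSS (mean ± SD, n = 3 in each group, as throughout), a log2 change of 4.19 (SE 0.40, limma adjusted p = 0.000729). Mptx1, a mucosal pentraxin second only to Igkc among the listed means of Control, fell from 3809 ± 2256 to 113 ± 106 FPKM (log2 change −5.38, SE 0.71, limma adjusted p = 0.00133). Changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Plet1 (ENSMUSG00000032068) lies on chromosome 9 from 50494525 to 50505482 and Mptx1 (ENSMUSG00000026531) on chromosome 1 from 174330518 to 174332873 (mm10). Which exons their FPKM covers is not given in the sources used here. Centring each library on the median of the listed features lowered every log2 change by 0.81, because the list holds mostly rises, and left 70 features higher and 118 lower. Under that shift rises can only shrink and falls only deepen. Loss of rises was thus built in, since the list was selected and holds mostly rises. Counts after centring, here and below, show only which rises exceed the median of the listed features, in a fit of the compared groups alone. The estimate of the spread differs in that fit, which also affects which features pass. They test neither the other rises nor the falls. Without the 2 libraries of conflicting description 502 features passed, all of them among the 571, and with groups taken from the description text 8 passed. Features listed for separating the groups of the titles would give few calls under other groups in any case, so the drop to 8 does not tell which text is right.

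**Figure D1:**
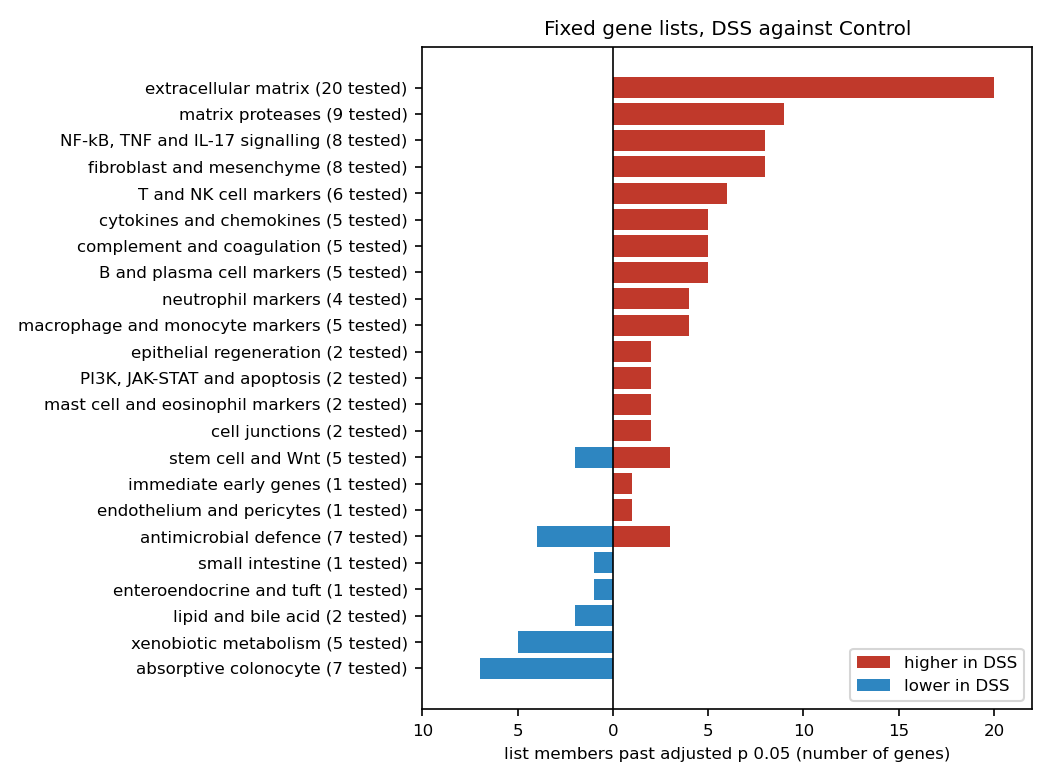
Members of each fixed gene list past an adjusted p of 0.05 in DSS against Control; bars to the right count genes higher in DSS, bars to the left genes lower in DSS, and the number tested stands beside each list name. All 20 tested matrix genes were higher and all 7 tested absorptive colonocyte genes were lower.

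All 5 tested cytokine and chemokine genes rose. The fixed list holds 39 such genes, of which 9 were listed and 5 passed the low-value filter. Other lists were covered in part too. Tested were 8 of 30 genes of NF-kB, TNF and IL-17 signalling, 4 of 22 neutrophil and 2 of 31 PI3K list genes. Absorptive colonocytes had 7 of 34 tested and xenobiotic metabolism 5 of 40. With 571 of 576 tested features called, a list whose tested members all changed says nothing about its other members. Cxcl5, a neutrophil-attracting chemokine, rose from 0.507 ± 0.211 to 10.5 ± 10.4 FPKM (log2 change 2.55), Cxcl1, another such chemokine, from 0.357 ± 0.201 to 2.64 ± 0.641 FPKM (1.42), Ccl2, a monocyte attractant, from 0.860 ± 0.111 to 3.71 ± 1.79 FPKM (1.26) and Tnf from 1.17 ± 0.461 to 3.56 ± 0.272 FPKM (limma adjusted p = 0.00356). Il1b, the gene of interleukin 1 beta, rose from 0.597 ± 0.278 to 13.6 ± 16.7 FPKM (log2 change 2.39). All 8 tested genes of NF-kB, TNF and IL-17 signalling rose, among them Nos2, the inducible nitric oxide synthase (log2 change 1.80), and Vcam1, an endothelial adhesion molecule (1.52). Both tested genes of the PI3K, JAK-STAT and apoptosis list, Pik3cd (log2 change 0.91) and Socs3 (1.19), rose. All 4 tested neutrophil markers rose: S100a8, a calcium-binding protein of neutrophils, from 0.310 ± 0.0781 to 9.61 ± 12.9 FPKM (log2 change 2.26), Csf3r (1.53), Mmp9 (1.32) and Retnlg (2.26). The rise of these genes differed widely between DSS libraries: without DSS replicate 2 the log2 change was 1.38 for Il1b, 1.25 for S100a8 and 0.79 for Mmp9, each still past the threshold. Il1b did not pass without Control replicate 2 (2.24), nor Retnlg without Control replicate 2 (2.23), DSS replicate 1 (2.17) or DSS replicate 2 (1.90). S100a8 rested on about 3 to 4 fragments per Control library. After centring, 2 of the 5 cytokine genes (Cxcl1 and Cxcl5), 4 of the 8 genes of NF-kB, TNF and IL-17 signalling, 0 of the 2 of the PI3K list and 1 of the 4 neutrophil markers (Retnlg) passed. Of the genes that did not, Il1b stood at 1.58, S100a8 at 1.46, Csf3r at 0.72, Mmp9 at 0.51, Ccl2 at 0.45 and Tnf at 0.29. The share of rises did not stand apart from that of the other calls for the cytokine list (two-sided Fisher's exact test, adjusted p = 0.606) or the NF-kB list (adjusted p = 0.553). With 456 rises among 571 calls, lists this short could not pass even with every member rising, so the test decides nothing for them.

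Among leukocyte markers, 4 of 5 tested macrophage and monocyte genes rose: Cd68 from 12.1 ± 2.19 to 27.3 ± 3.70 FPKM (log2 change 1.12), Ccr2 (1.17), Fcgr1 (1.02) and Cx3cr1 (0.97). The fifth, Chil3, stood at 0.0767 ± 0.0351 and 0.617 ± 0.537 FPKM (limma adjusted p = 0.258). All 6 tested T and NK cell markers rose, with Trac, the T cell receptor alpha constant segment, at 3.74 ± 0.439 and 8.96 ± 2.27 FPKM (log2 change 1.05), Cd4 at 3.20 ± 0.470 and 6.89 ± 0.979 FPKM (0.91), and the costimulatory and inhibitory receptors Icos (1.16) and Ctla4 (1.15) also higher. All 5 tested B and plasma cell markers, which are immunoglobulin constant genes, rose. Ighg2c, a heavy chain constant gene of IgG, rose from 9.24 ± 2.04 to 147 ± 75.9 FPKM (log2 change 3.75), Ighg2b from 56.5 ± 41.8 to 339.0 ± 200.3 FPKM (2.61), Ighg1 from 1.91 ± 0.2001 to 9.65 ± 2.21 FPKM (1.86) and Igkc, the kappa light chain constant gene, from 4157 ± 366 to 10909 ± 2141 FPKM (1.38). Igkc made up 19.4 to 24.1% of the listed FPKM in Control libraries and 35.6 to 37.9% in DSS libraries. In a grouping by annotation chosen after the data were seen, 50 of 52 tested immunoglobulin variable segments rose and 2, Ighv5-9-1 and Iglv2, fell. The variable segments Ighv1-54 (log2 change 5.02, SE 0.62), Ighv13-2 (4.74), Igkv14-126 (4.64), Ighv9-3 (4.20), Ighv2-3 (4.07), Igkv8-28 (3.78) and Ighv1-39 (3.77), with Plet1, were the 8 largest rises that met the naming rule. Near-identical segments can share reads, so values of single segments are uncertain. Both tested mast cell genes, Mcpt4 (log2 change 0.81) and Cpa3 (0.64), rose, and after centring neither passed and the change of Cpa3 was −0.17. After centring, 0 of the 5 macrophage, 0 of the 6 T and NK and 2 of the 5 B and plasma cell markers passed. The share of rises did not stand apart from that of the other calls for the T and NK or the B and plasma cell list (two-sided Fisher's exact test, adjusted p = 0.606 for each). Every tested member of both lists rose and the test still could not pass, so it decides nothing for them.

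**Figure D2:**
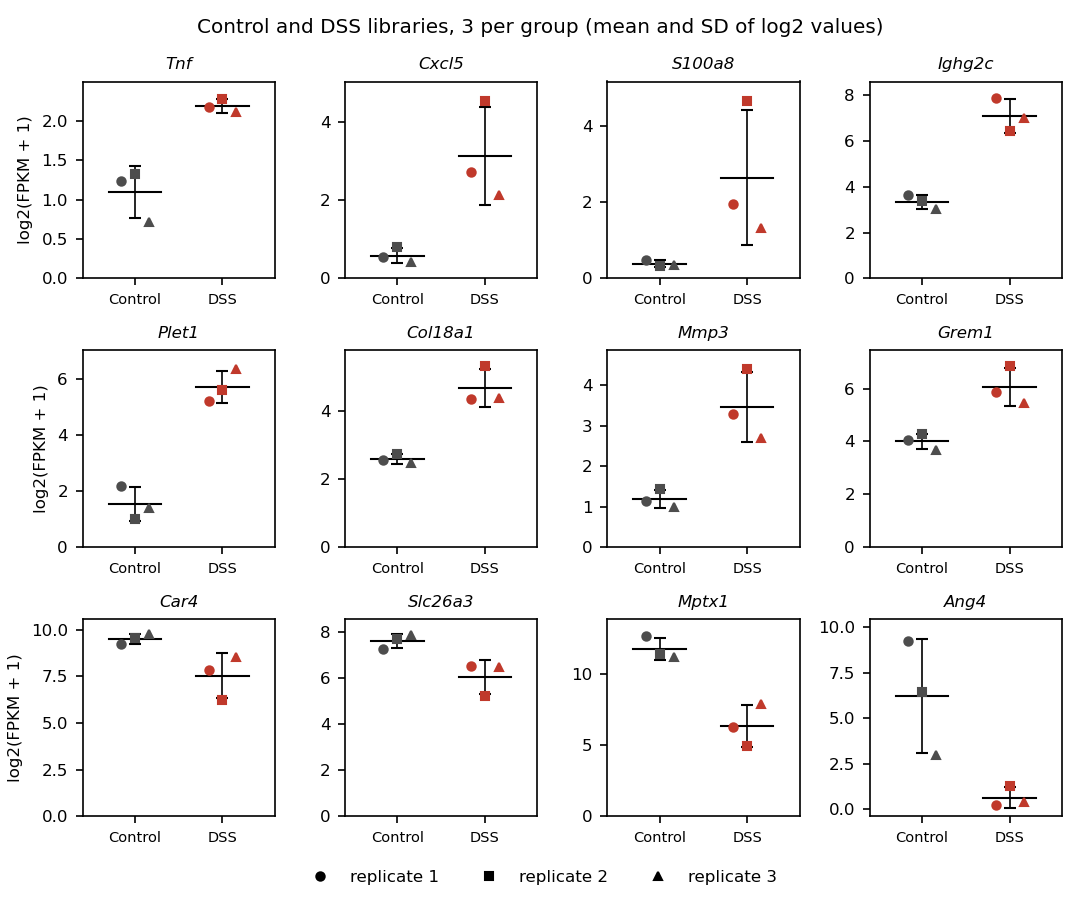
Expression as log2(FPKM + 1) of 12 genes in Control and DSS libraries, each point a library (marker shape gives the replicate number), lines and bars the mean ± SD of the log2 values for n = 3 libraries. Tnf to Grem1 are higher and Car4 to Ang4 lower in all 3 DSS libraries than in all 3 Control libraries, and Ang4 ranges from 6.87 to 608 FPKM among the Control libraries.

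All 20 tested genes of extracellular matrix and collagen, all 9 matrix protease genes and all 8 fibroblast genes rose. Col1a2, a chain of type I collagen, rose from 16.8 ± 1.73 to 60.6 ± 26.1 FPKM (log2 change 1.72), Col18a1 from 5.06 ± 0.593 to 25.7 ± 10.9 FPKM (2.07), Bgn, the proteoglycan biglycan, from 29.0 ± 3.01 to 84.7 ± 17.1 FPKM (2.92-fold) and Lox, a collagen cross-linking enzyme, from 2.52 ± 0.692 to 14.0 ± 6.18 FPKM (2.04). The proteases Mmp10 (log2 change 2.41), Mmp3 (2.28), Mmp2 (1.53) and Ctsk (1.40) rose, and so did the fibroblast genes Grem1, a BMP antagonist (2.05), Igfbp5 (1.92), Igfbp4 (1.86) and Thy1 (1.24). All 20 matrix genes and all 8 fibroblast genes were highest in DSS replicate 2, as were 294 of all 456 features that rose, whereas all 6 T and NK and all 5 B and plasma cell markers were highest in DSS replicate 1. All 20 matrix genes remained past the threshold without DSS replicate 2, as did 548 of all 571 calls. With 456 rises among 571 calls, the share of rises in the matrix list did not stand apart after adjustment over the 12 lists with 5 or more calls (two-sided Fisher's exact test, adjusted p = 0.0777). Nor did that of the protease (0.518), fibroblast (0.553) or complement list (0.606), which were too short to pass even with every member rising. Complement and coagulation genes also rose in 5 of 5, among them C3 from 39.4 ± 8.75 to 128 ± 33.8 FPKM (log2 change 1.66), C4b (1.53), Plaur (1.15) and Plau (0.98). After centring, 4 of the 20 matrix, 2 of the 9 protease, 3 of the 8 fibroblast and 1 of the 5 complement genes were past the threshold, each higher in DSS.

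All 7 tested absorptive colonocyte genes fell, a share that differed from that of the other calls (two-sided Fisher's exact test, adjusted p = 0.000139). Fisher's test counts genes as independent, which genes of the same libraries are not, so its p-values do not measure the spread between libraries. Car4, a membrane carbonic anhydrase, fell from 728 ± 132 to 224 ± 148 FPKM (log2 change −1.96), Slc26a3, the chloride-bicarbonate exchanger of the colon surface, from 198 ± 41.1 to 71.3 ± 30.7 FPKM (−1.55), Slc20a1, a phosphate transporter, from 109.8 ± 22.1 to 44.8 ± 22.7 FPKM (−1.40) and Slc51b, a subunit of the bile acid exporter, from 22.4 ± 5.78 to 7.77 ± 3.53 FPKM (−1.48). All 5 tested genes of xenobiotic and retinol metabolism fell (Fisher's exact test, adjusted p = 0.00185): the carboxylesterases Ces1f (log2 change −1.27) and Ces2c (−1.01), the glutathione transferase Gstm1 (−1.03), the sulfotransferase Sult1a1 (−1.30), which both lists hold, and Ugt1a1. Apob (−0.93) and Fabp6 (−0.83), of the lipid and bile acid list, fell, and Fabp6 is also the single tested member of the small intestine list. Sh2d6, of the enteroendocrine and tuft list, fell (−1.03). Trpm6, an epithelial magnesium channel, fell from 34.9 ± 6.80 to 8.01 ± 3.87 FPKM (−2.06). Without DSS replicate 2 the changes of Car4 (−1.30), Slc20a1 (−0.93) and Sult1a1 (−0.83) shrank by more than 1.5 times and 3 of the 5 xenobiotic genes passed. The number of colonocyte genes past the threshold was 3 without Control replicate 2 and 4 without the 2 libraries of conflicting description, and that of xenobiotic genes was 1 without either Control replicate 2 or Control replicate 3. Without Control replicate 2 the calls of Slc20a1 (−1.32), Slc26a2 (−0.97), Slc4a4 (−0.54), Sult1a1 (−1.34), Gstm1 (−1.04), Ces2c (−1.01) and Ugt1a1 (−0.65) were lost. Without Control replicate 3 the same held for Slc26a2 (−1.005), Sult1a1 (−1.13), Gstm1 (−0.93), Ces2c (−0.86) and Ugt1a1 (−0.54). Without DSS replicate 1 Slc4a4 (−0.69) and Ugt1a1 (−0.56) lost theirs. Without DSS replicate 2 Ces2c (−0.69) and Ugt1a1 (−0.59) did. Without the 2 libraries of conflicting description Apob (−0.89), Fabp6 (−0.67), Ces2c (−1.05), Slc20a1 (−1.44), Slc26a2 (−1.12) and Slc4a4 (−0.85) did not pass, nor did Prom1 (1.14) and Retnlg (2.69) among the rises.

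Antimicrobial and defence genes moved both ways, with 3 of 7 tested genes higher and 4 lower (Fisher's exact test, adjusted p = 0.0997). Slpi, a secreted protease inhibitor, rose from 6.52 ± 1.45 to 49.96 ± 11.2 FPKM (log2 change 2.76, SE 0.31), and Saa3 and Nos2 also rose. Ang4, an antimicrobial ribonuclease, stood at 608, 84.5 and 6.87 FPKM in the Control libraries and at 0.18, 1.44 and 0.29 FPKM in the DSS libraries, about 2 to 17 fragments, and fell by 5.58 on the log2 scale (SE 1.27, limma adjusted p = 0.00493). Wfdc2 fell from 88.4 ± 15.2 to 36.2 ± 4.21 FPKM (log2 change −1.26), and Retnlb and Saa1 also fell. Other named falls were Retnla (−2.63), Sycn (−2.43), 2310079G19Rik (−2.41), 5430427M07Rik (−2.39) and Gm21885 (−2.30). 5430427M07Rik is annotated as antisense, and the use of strand in counting is not given in the sources used here, so its reads cannot be told from those of the opposite strand. Of 5 tested stem cell and Wnt genes, Ascl2, a transcription factor of crypt stem cells (−1.38), and the Wnt target Axin2 (−0.94) fell, and the Wnt-pathway ligands Rspo3 (0.97) and Wnt5a and the surface protein Prom1 (1.17) rose. The stem cell list did not stand apart either (adjusted p = 0.530). After centring, 0 of these 3 rises were past the threshold. The junction genes Cldn1 (1.46) and Cldn5 (0.90), the latter also the single tested member of the endothelium list, the regeneration-list gene Anxa8 (2.06, 28.2 ± 9.72 to 119 ± 33.6 FPKM) and the immediate early gene Egr1 (1.96) rose. Centring kept the calls of Cldn1 and Anxa8 and removed those of Cldn5 (0.09) and Egr1 (1.15), and it kept 2 of the 3 antimicrobial rises. In every list the number of members past the threshold was the same adjusted over the list alone. The lists for interferon response, goblet cells and mucus, proliferation, smooth muscle, enteric neurons and glia, mitochondrial respiration, circadian clock, pancreas and sex-linked genes had no member among the 912 features, and those for antigen presentation, erythrocytes, adipose tissue, skeletal muscle and squamous epithelium had members only below the low-value filter. Of 12 genes set in advance, Il1b, Tnf and S100a8 were listed in Control and DSS, Reg3b in BXD_L and Car1 in BXD_H, and the other 7 (Il6, Il17a, Lcn2, Muc2, Tjp1, Ocln and Aqp8) were in none of the lists.

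The comparison of BXD_L with DSS asks what the low dose changed in mice with colitis, and only 3 features allowed it. All 3 are immunoglobulin variable segments that rose in DSS, and all 3 fell. Ighv13-2 (chromosome 12, 114357759 to 114358218) stood at 126 ± 105 FPKM in DSS and 7.91 ± 5.82 in BXD_L, a log2 change of −3.77 (SE 0.69, limma adjusted p = 0.000307), against 3.37 ± 2.27 in Control. Igkv1-99 (chromosome 6, 68541644 to 68542422) stood at 9.33 ± 4.48 FPKM in DSS and at 1.65, 0.48 and 0 FPKM in the BXD_L libraries (log2 change −2.63, SE 0.40, limma adjusted p = 0.000139), against 1.15 ± 0.683 in Control. Ighv1-54 (chromosome 12, 115193675 to 115194134) fell from 136 ± 48.0 to 41.7 ± 6.38 FPKM (log2 change −1.62, SE 0.62, limma adjusted p = 0.0244). The fall of Ighv1-54 was no longer past the threshold without DSS replicate 1 (−1.58), DSS replicate 2 (−1.38) or BXD_L replicate 1 (−1.49), or with a pseudocount of 0.1 (−1.65). With groups from the description text its change was 0.50. The 3 of 3 features on the Control side of the DSS mean (exact binomial 95% interval 29.2 to 100%) are no test of reversal. With 3 features chance allows any share (0 to 100% for a simulated group that differs from DSS in nothing), and all 3 passed against DSS, as features chosen for that difference would. The median share of the DSS shift removed was 79.6%, the value of Ighv13-2, against −0.23% in simulation. The simulated features were not selected for a difference from DSS, so this gap is no evidence of reversal either.

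Against Control, Ighv1-54 remained higher in BXD_L, at 41.7 ± 6.38 against 4.91 ± 6.30 FPKM (log2 change 3.39, SE 0.62, limma adjusted p = 0.000648). Ighv13-2 (log2 change 0.97, adjusted p = 0.280) and Igkv1-99 (−0.39, adjusted p = 0.352) did not pass limma's test, and their changes ranged from 0.41 to 1.55 and from −0.76 to −0.06 when single libraries were left out. With groups from the description text, DSS replicate 3 was the only BXD_L library of most features tested, so no count is given.

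**Figure D3:**
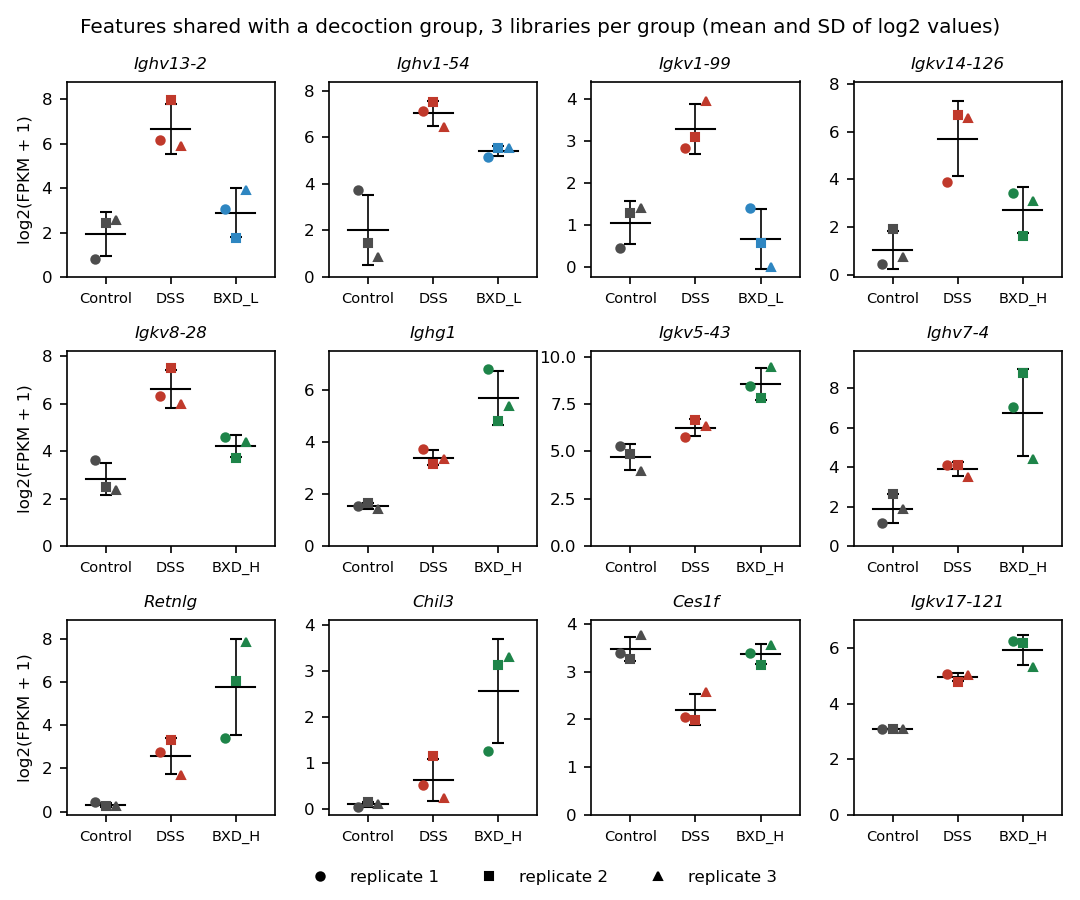
Expression as log2(FPKM + 1) of 12 features that Control and DSS share with BXD_L (first 3 panels) or BXD_H (other panels), each point a library, lines and bars the mean ± SD of the log2 values for n = 3 libraries. Ighv13-2, Ighv1-54, Igkv1-99, Igkv14-126 and Igkv8-28 are lower with the decoction than in DSS, whereas Ighg1, Igkv5-43, Ighv7-4, Retnlg, Chil3 and Igkv17-121 have higher means than in both other groups and the mean of Ces1f lies near that of Control.

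The comparison of BXD_H with DSS asks the same of the high dose, over 17 tested features. Of these, 12 rose, 4 fell and 1, Hkdc1, did not pass (0.927 ± 0.828 against 0.227 ± 0.0473 FPKM, limma adjusted p = 0.0506). Retnlg, a neutrophil-derived resistin-like protein (ENSMUSG00000022651, chromosome 16, 48872621 to 48874496), rose from 5.64 ± 3.36 to 100.1 ± 112.6 FPKM (log2 change 3.17, SE 0.86, limma adjusted p = 0.00652), with 9.50, 64.5 and 226 FPKM in the 3 BXD_H libraries, about 97, 696 and 1666 fragments. Chil3, a chitinase-like protein of myeloid cells, rose from 0.617 ± 0.537 to 6.06 ± 4.06 FPKM (1.93). Among immunoglobulin genes, Ighg1 rose from 9.65 ± 2.21 to 59.9 ± 45.2 FPKM (2.28), Igkv5-43 from 77.9 ± 23.3 to 424 ± 251 FPKM (2.31), Ighv7-4 from 14.3 ± 3.51 to 199.7 ± 219.3 FPKM (2.86) and Igkv17-121 from 30.3 ± 3.18 to 62.8 ± 20.9 FPKM (0.97). Igkv14-126 fell from 69.0 ± 48.1 to 6.51 ± 3.92 FPKM (−2.97, SE 0.73) and Igkv8-28 from 107.8 ± 64.6 to 18.5 ± 5.68 FPKM (−2.37, SE 0.47). Ces1f rose from 3.70 ± 1.09 to 9.39 ± 1.52 FPKM (1.16, SE 0.25), close to the 10.3 ± 2.07 FPKM of Control. The remaining features, named here because they complete the set, were Klk15 (−1.36) and Tgm5 (−0.54), which fell, and Kcnh3 (0.56), Bst1 (0.74), Alpl (0.76), Fgr (0.97) and Cd300ld (limma adjusted p = 0.00652), which rose. The change of Ighv7-4 ranged from 1.85 without BXD_H replicate 2 to 4.03 without BXD_H replicate 3. Centring lowered every log2 change by 0.99 and left none of the 12 rises past the threshold, with Retnlg at 2.18, Ighv7-4 at 1.88, Igkv5-43 at 1.33, Ighg1 at 1.30, Ces1f at 0.17 and Igkv17-121 at −0.02. Most of these 17 features rose and centring subtracts their own median, so a loss of rises was built in. The spread was also estimated anew from these groups alone, with the SE going from 0.43 to 0.72 for Ighg1 and from 0.45 to 0.42 for Chil3. How much of the loss each step caused was not tested. The loss cannot tell a difference in scale between these files from the rises. With groups from the description text 6 features passed.

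Against Control, 12 of the 17 features were higher in BXD_H and none lower in limma's test, with 14 at an unadjusted p under 0.05. The largest differences by the naming rule were Retnlg (log2 change 5.43, SE 0.86), Ighv7-4 (4.87), Ighg1 (4.14), Igkv5-43 (3.87), Igkv17-121 (2.83) and Igkv8-28 (1.41), and Chil3 was higher by 2.47. Igkv8-28 did not pass without Control replicate 2 (1.25), Control replicate 3 (1.17) or BXD_H replicate 1 (1.23), nor without the 2 libraries of conflicting description (1.17), and its change was −0.44 after centring, which lowered every log2 change by 1.85 and gave 3 rises and 5 falls. Ces1f differed by −0.11 (SE 0.25, limma adjusted p = 0.665) and Igkv14-126 by 1.67 (SE 0.73, limma adjusted p = 0.0573). Of 15 tested features that had changed in DSS, 6 lay on the Control side of the DSS mean in BXD_H (40.0%, exact binomial 95% interval 16.3 to 67.7%) and 9 lay farther from Control, of which 5 and 9 were past the threshold against DSS. An unchanged group sharing the DSS libraries gave 55.1% on the Control side in simulation, with a central 95% range of 27.3 to 81.8%. The median share of the DSS shift removed was −90.7%, the value of Alpl, against 2.65% in simulation. The simulated features were not selected for a difference from DSS, as the listed ones may be. A large value of either sign could come from that selection, so this gap is no evidence of a move away from Control. The share of features on the Control side was 60.0% without Control replicate 3, 55.6% without the 2 libraries of conflicting description, 54.5% without DSS replicate 2 and 62.5% among features past an adjusted p of 0.01 in DSS, since fewer features then counted as changed in DSS.

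The doses could be compared at 2 features listed for both, and neither passed limma's test, with 0 at an unadjusted p under 0.05. Dbp, a transcription factor under circadian control, stood at 5.67 ± 2.14 FPKM in BXD_H and 4.93 ± 1.01 FPKM in BXD_L (log2 change 0.13, SE 0.29, adjusted p = 0.671). Ighv2-9 stood at 12.2 ± 8.32 and 5.98 ± 3.89 FPKM (log2 change 0.81, SE 0.69, adjusted p = 0.542), and its change ranged from 0.23 without BXD_L replicate 2 to 1.58, past the threshold, without BXD_H replicate 3. The change of Dbp ranged from −0.09 to 0.39 when single libraries were left out. No feature was listed for Control, DSS and both doses together, so the effects of the doses against DSS were not compared with each other.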

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

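All alternatives were planned except the centring of gene lists, added after the data were seen. The reversal shares stayed inside their binomial intervals. For BXD_H against Control 12 rises became 3 rises and 5 falls when centred, with 3 calls kept and Bst1 turned from a rise to a fall, and the other settings gave 11 to 14 features. For DSS against Control the 571 features became 188 (70 higher, 118 lower) with median-centred values, since centring subtracts the excess of rises in the list, 877 (708 higher, 169 lower) without the low-value filter, which tested 912 features, and 319 with a log2 change beyond 1. With the groups of the description text they became 8, and leaving out single libraries gave 528 to 562. With the groups of the description text, 576 features were tested for BXD_L against DSS and against Control, and 19 between the doses. Most of these have no value in the BXD_L files, so DSS replicate 3 alone stood for BXD_L. No count of calls is given for them. For BXD_H against DSS, 16 features became 4 (0 higher) when centred, 6 with the groups of the description text and 10 with a log2 change beyond 1. For the 2 doses, 0 features became 0 to 1 when single libraries were left out. Beyond the changes in the number of features tested, the cause was not tested.

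Direction reversed in 6 named results: after centring, Igkv8-28 in BXD_H against Control (−0.44), Igkv17-121 in BXD_H against DSS (−0.0152) and Cpa3 in DSS against Control (−0.17), by the subtraction itself, with the groups of the description text Ighv1-54 in BXD_L against DSS (0.50) and Igkv1-99 in BXD_L against Control (0.61), and without BXD_H replicate 1 Dbp between the doses (−0.0909, with single libraries left out −0.0909 to 0.39). Of 105 named results, 104 kept their call with a pseudocount of 0.1, 98 without the 2 libraries of conflicting description, 55 of 97 after centring and 19 with the groups of the description text. Same-numbered libraries did not deviate together (correlations −0.05, 0.02 and 0.08 for Control and DSS, −0.25, −0.11 and −0.16 for DSS and BXD_H). That gives no sign of pairing by number. With so few libraries and features selected for group difference, pairing or a shared batch cannot be excluded. The replicate block gave 569 features for DSS against Control, 16 for BXD_H against DSS and 3 for BXD_L against DSS, and kept the call of all 105 named results. The count-based alternatives (DESeq2 and edgeR settings and a count filter) and camera were not run, because the files hold FPKM of selected features. Depth limits the lowest genes: S100a8 and Retnlg rest on 2 to 4 fragments per Control library.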

Other observations

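The BXD_H libraries list 76 features without a value in Control or DSS, so levels can be given but no direction. Car1, the abundant carbonic anhydrase of colonocytes, stood at 402 ± 46.6 FPKM (n = 3). Sqle, the squalene epoxidase, a member of the fixed lipid list, stood at 28.4 ± 4.42 FPKM. Other enzymes of sterol synthesis in these libraries, picked after their values were seen, were Hmgcs1 at 112 ± 22.4 FPKM, Fdft1 at 40.1 ± 5.01 FPKM, Cyp51 at 39.95 ± 7.81 FPKM, Msmo1 at 36.8 ± 7.27 FPKM, Hsd17b7 at 8.27 ± 1.43 FPKM and Lss at 7.71 ± 1.93 FPKM. The chemokine Ccl8 stood at 50.5 ± 8.91 FPKM and the variable segments Ighv5-17 and Ighv1-12 at 248 ± 197 and 164 ± 129 FPKM. The BXD_L libraries list 5 such features, among them Reg3b, an antimicrobial lectin, at 0.43, 0.26 and 0.18 FPKM, Clec2i, a C-type lectin, at 1.12 ± 0.0651 FPKM and Ighv3-5 at 20.2 ± 9.05 FPKM.

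The tests below were chosen after the results were seen, except leaving out DSS replicate 2 for the matrix genes and the simulation of an unchanged group. In DSS against Control, fitted on those 6 libraries alone, 1 of the 10 splits of the libraries, the real one, gave as many features as the real 574, and the highest of the other splits gave 2. For BXD_H against DSS the real split gave 14 features and the highest other split 0, and for BXD_H against Control 13 and 0, again 1 of 10 splits. With 10 splits a share under 0.05 is out of reach, and features listed for separating these groups would give few calls in other splits in any case, so the splits test nothing beyond the selection.

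Neutrophil genes differed widely between the 3 BXD_H libraries. Retnlg stood at 9.50, 64.5 and 226 FPKM in replicates 1, 2 and 3, Mmp8, the neutrophil collagenase, at 1.22, 9.25 and 21.7 FPKM and Ngp, a neutrophil granule protein, at 0.76, 4.23 and 17.5 FPKM. A difference in depth or scaling is argued against by the other 92 listed features, whose median log2 ratio of replicate 3 to replicate 1 was 0.42 (quartiles −0.16 and 1.07), against 4.05 to 4.56 for the 3 neutrophil genes, although single features outside the list reached as far or nearly so (Cyp2b10 4.75, Ighv1-12 3.96). A candidate explanation is that the tissue pieces, or the blood in them, differed in neutrophil content, with all 3 listed members of the neutrophil list lowest in replicate 1 and highest in replicate 3. This stays open, because 36 of the 95 listed features take that order and the members were seen before the test.

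In the DSS group, matrix and fibroblast genes were highest in replicate 2 and lymphocyte markers in replicate 1. The 11 T, NK, B and plasma cell markers that rose had a median log2 excess in replicate 2 over the mean of the other DSS libraries of −0.16. The matrix genes had 0.90. Depth or scaling of replicate 2 alone would shift both sets alike, so it cannot give the gap between them. The markers were already seen to be highest in replicate 1, so these values restate the pattern. A part played by scaling stays open, because all 456 features that rose had a median excess of 0.32 and 294 were highest in replicate 2. The rise of the matrix genes was not confined to replicate 2, since 20 of 20 passed without it. This does not set the matrix genes apart, because 548 of all 571 calls also passed without it. Features listed for separating the groups would mostly pass in any case, so that test could hardly have failed. A hypothesis that the libraries may come from pieces or mice with different degrees of mesenchymal and lymphoid change also stays open, and no biological explanation was tested, since the labels give no feature of single mice.

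Of 15 features changed in DSS and shared with BXD_H, 9 lay farther from Control than in DSS, among them Retnlg, Ighg1, Igkv5-43, Fgr and Cd300ld. With other settings the share on the Control side ran from 35.3% (pseudocount 0.1) to 62.5% (adjusted p under 0.01 in DSS). It was 60.0% without Control replicate 3 and 55.6% without the 2 libraries of conflicting description. Without Control replicate 3, 6 features still lay on the Control side and 4 farther, since fewer features then counted as changed in DSS. Chance through the shared DSS libraries could give the larger part farther from Control: an unchanged group had 55.1% of features on the Control side, with a central 95% range of 27.3 to 81.8% that holds the observed 40.0%. The choice of listed features may also set it, since 93.3% of these features passed the test against DSS, as a list chosen for that difference would show. Neither can be told apart from an effect of the high dose, because the features outside the lists are not analysed here.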
